A study of Mus musculus with 3 samples.

How the data were processed

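ATAC-seq libraries were made from the apical part of mouse first molars, with 2 libraries labelled control (Arid1a fl/fl) and 1 labelled mutant (Gli1-CreER;Arid1a fl/fl). Per the labels' protocols, tamoxifen was given at postnatal day 3.5, molars were taken at postnatal day 7.5 and digested with collagenase, and each library was made from 5000 cells. Reads were processed with FastQC 0.11.8, cutadapt 1.18, Bowtie2 2.3.5, Picard, MACS2 2.1.1, bedtools and edgeR, per the submitters' processing notes, which give mm10 as the genome. Reads, alignments and counts per library were not used here, so neither depth per library nor mutant against control could be given.

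A pair of deposited tables was analysed, an annotation of windows and a list of motif sites. Per the file headers, HOMER's annotatePeaks program was run on a union list of peaks with 1 motif, that of Zac1 (Plagl1), in a window around the centre of each region, without gene annotation. How the regions of the union list were chosen is not given in the sources used here. The deposited GC content is a fraction of the bases in each window, per the file headers, and was turned into percent. The deposited CpG value is CpG dinucleotides over the steps between neighbouring bases, and is given here per 100 steps. As checked on the values, the GC count was whole within 0.01 in all but 2 windows, and the CpG count in all but 1. The deposited score of each site is HOMER's log-odds score for the motif, and the file does not state its log base. All sites of the annotation were found in the site list with the same coordinates (100%). The file positions are in mm10, and are printed counting from 1.

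From these files were computed the position of windows relative to genes, the share of windows and genes with a site, and comparisons with random placements and shuffled sequence. Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10. Because the table carries no strand, the distance of a window's midpoint to either end of a gene was used in place of the transcription start, and a gene had a window when a midpoint lay within 1 kb of either end. A window was assigned to every gene that its midpoint lay in or within 1 kb of, so neighbouring genes can share a window. Windows of the same width were placed at random 1000 times on the same chromosome, avoiding neither gaps in the assembly nor GC differences. For site counts, 100 sets of random sequences were drawn, called shuffled windows here, since the bases of the windows were not available. Each kept a window's summed number of G and C bases and its number of CpG dinucleotides, with 1000 mixing swaps per window. G and C were drawn in equal numbers, as were A and T, but for an odd base. The motif matrix was recovered from site sequences and scores, with a largest error of 5.3e-07 in score, and used to score the shuffled windows. Of 667 possible sequences at or above the lowest score, 642 were seen. The excess of a single sequence, standardised by the square root of its shuffled mean, was set against the largest such excess of any sequence in each shuffled set.

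Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Fixed gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the lists, at 0.05. For windows the background was all other protein-coding genes, and for sites it was the genes with a window. The lists overlap: Plagl1 and Cdkn1c are in both the cell cycle inhibitors and the imprinted genes, Bmp2 and Bmp4 are in both the odontoblast and the BMP lists, Wnt10a is in the odontoblast and Wnt lists, and Sfrp2 and Axin2 are in the dental mesenchyme and Wnt lists. Differences of medians were tested with 100000 permutations, and the evenness of site positions against simulated positions drawn uniformly. Windows and genes are not biological replicates. Fisher's exact tests treat genes as independent, and no allowance was made for members of a list or family that lie side by side on a chromosome. Their p-values can therefore be too small. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.

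The gene lists, the tests of windows at gene ends and of scores by class, their alternatives and the rule for named genes were written before the data were examined. That rule names Plagl1, Arid1a and Gli1, up to 6 members per list with a window at a gene end (most assigned windows first, then alphabetical), the hedgehog and cell cycle inhibitor genes without any assigned window, the 10 genes with the most assigned windows, and the 10 highest-scoring sites. Some genes of the lists are not reported here by name. The comparison with shuffled windows, the share of sites by class, the site tests of the lists and the gene families were chosen after the files were seen. The scripts for placements, shuffled windows and list tests were tested on simulated data. Random windows gave a fold of 1.00 near gene ends, shuffled windows without added sites a ratio of 1.00, and none of the lists was called when sites were given to genes at random. With 90% of hedgehog members given a site, the list was called in 100% of 40 sets. Alternatives tried were other distances to genes, other backgrounds, higher-scoring sites alone, the central 50 bp of each window, shuffles that keep GC content alone, models with GC and CpG content as covariates, and placements anywhere in the genome.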

Results

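Open chromatin was assayed by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into accessible DNA, in cells from the apical part of the first molars of C57BL/6 mice. The 3 libraries were labelled as 2 from Arid1a fl/fl controls and 1 from a Gli1-CreER;Arid1a fl/fl mutant. Arid1a is a subunit of SWI/SNF chromatin remodelling complexes, and Gli1-CreER deletes the floxed gene in cells that express the hedgehog target gene Gli1. The series concerns how Arid1a, the zinc finger transcription factor Plagl1 (also called Zac1) and hedgehog signalling bear on cell cycle arrest in tooth root progenitors. The values analysed here are pooled over libraries. They comprise 13500 open chromatin windows of 201 bp on 21 chromosomes of mm10, and 5753 sites of the Plagl1 binding motif found by sequence in those windows. Because the windows carry no value per library, the mutant and control libraries were not compared here, the read depth behind a window is unknown, and no value below has a replicate error. How the regions were chosen is not given in the sources used here, so a gene without a window may still have open chromatin, and the shares below describe this list of regions. A window marks where the motif search was made, and a motif site is a sequence match, not a measurement of Plagl1 binding.

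The question of where the windows lay in the genome was answered by their distance to annotated genes. Open chromatin windows gathered at the ends of protein-coding genes: 9078 windows (67.2%) had their midpoint within 1 kb of a gene end, where random placements on the same chromosome put 3.20% ± 0.152 (SD, 1000 placements). That is a 21-fold excess. Windows inside genes but over 1 kb from any end were fewer than by chance, 2621 (19.4%) against 38.8% (fold 0.501), as were windows outside genes, 1801 (13.3%) against 58.1% (fold 0.230). These classes make up all windows, so the excess near gene ends by itself lowers the other shares. It would lower both by the same factor, but the folds were 0.501 inside genes and 0.230 outside. Among windows away from gene ends, more thus lay inside genes than among the placements, a split that was not tested by itself. The median distance to the nearest gene end was 131 bp for windows near a gene end, 7392 bp for those inside genes and 18523 bp for those outside. Counting all annotated genes, 72.6%, 80.8% and 89.8% of windows lay within 1, 3 and 10 kb of a gene end, or 11.2-fold, 4.95-fold and 2.36-fold the random shares. Each of these shares differed from the placements with a two-sided empirical p of 0.002, the smallest that 1000 placements can give, before and after adjustment. The windows near gene ends were rich in G and C, with a median GC content of 68.2%, against 64.7% inside genes and 55.7% outside. The placements were not matched on GC content, and the gene table gives no strand, so a gene end is either its start or its finish.

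Of the genes that the series is about, Plagl1 had 1 window, at chromosome 10, 13090738 to 13090938, with its midpoint 6 bp from the gene end, and that window held no site of the Plagl1 motif. Arid1a had no window within 1 kb of its ends, but 3 windows on chromosome 4 lay inside the gene, also without a site. The closest of them lay 2581 bp from a gene end. Gli1 had 1 window, inside the gene at chromosome 10, 127339470 to 127339670 and 2009 bp from a gene end, with 2 sites of scores 5.93 and 5.52. In all, 10205 of 21887 protein-coding genes (46.6%) had a window within 1 kb of an end.

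Gene lists fixed before the files were seen were used to ask which pathways and cell types had a window of the region list at their gene ends. Genes of the cell cycle had such windows more often than other protein-coding genes. Of the cell cycle inhibitors, 19 of 21 (90.5%) had a window, with an odds ratio of 10.9 (95% interval 2.63 to 96.5, adjusted p = 0.000185). They included Rb1, the retinoblastoma protein that restrains entry into S phase, the Cdk inhibitor Cdkn2d, the antiproliferative genes Tob1, Btg1 and Btg2, and the p53 target Ccng1. No member of this list was without an assigned window: Cdkn1a, the p53-induced Cdk inhibitor, had 2 windows inside the gene, and Trp53, which encodes p53, had 1. Of the genes that drive the cycle, 30 of 35 (85.7%) had a window, with an odds ratio of 6.89 (95% interval 2.64 to 22.7, adjusted p = 2.6e-05). These included E2f3, a transcription factor of the G1 to S transition, the replicative helicase subunit Mcm7, the topoisomerase Top2a, the mitotic kinases Aurka and Aurkb, and the spindle checkpoint kinase Bub1.

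Signalling and chromatin genes followed the same direction in part. Hedgehog pathway genes had a window in 17 of 22 cases (77.3%), an odds ratio of 3.90 (95% interval 1.38 to 13.5, adjusted p = 0.00825). Among them were Smo, the membrane protein that transduces the hedgehog signal, the co-receptors Boc and Cdon, Disp1, which releases the ligand from producing cells, the ligand Dhh, and the ciliary protein Evc. The ligands Shh and Ihh and the ligand-binding inhibitor Hhip had no assigned window. Genes of BMP and TGF-beta signalling had windows in 24 of 32 cases (75%, odds ratio 3.44, adjusted p = 0.00465), among them the signal transducers Smad3 and Smad7, the ligand Tgfb1 and the receptors Acvr1, Acvr2a and Tgfbr2. SWI/SNF subunits had them in 22 of 27 cases (81.5%, odds ratio 5.05, adjusted p = 0.00125), among them the ATPase Smarca2, the Arid1a paralogue Arid1b, and Bcl7c, Bicra, Bicral and Dpf1. Wnt pathway genes did not differ from other genes, with 15 of 40 (37.5%, odds ratio 0.686, adjusted p = 0.308). Their members with a window included Ctnnb1, which encodes beta-catenin, its destruction complex scaffold Apc, the transcription factor Tcf7l1 and the receptors Fzd1, Fzd2 and Fzd8.

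Markers of odontoblasts and dental mesenchyme, and imprinted genes, did not differ from other genes. Odontoblast and osteogenic genes had a window in 14 of 29 cases (48.3%, odds ratio 1.07, adjusted p = 0.855), among them Col1a1 and Col1a2, the chains of type I collagen of bone and dentine, the phosphatase Alpl, the ligand Bmp2 and the homeobox genes Dlx3 and Dlx5. Genes of dental mesenchyme and its progenitors had one in 7 of 20 (35%, odds ratio 0.616, adjusted p = 0.397), including Barx1, Sox9, Pdgfrb, Lrig1, Nt5e and Pthlh. Imprinted genes, a group that includes Plagl1 itself, had one in 7 of 24 (29.2%, odds ratio 0.471, adjusted p = 0.126), including Grb10, Igf2r, Cdkn1c, Ndn, Peg12 and Plagl1.

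Of the other cell types that a digest of the molar could hold, markers of dental epithelium and of immune cells were less often at a window than other genes, and those of the other 3 types did not pass the test at this distance. Dental epithelium markers had 1 of 16 (6.25%, odds ratio 0.0762, adjusted p = 0.00198), the enamel matrix gene Ambn. Immune markers also had 1 of 16 (odds ratio 0.0762, adjusted p = 0.00198), the T cell receptor complex gene Cd3d. Endothelial markers had 3 of 13 (odds ratio 0.343, adjusted p = 0.126), namely the VEGF receptor Kdr, the transcription factor Erg and the receptor Tie1. Glial and neuronal markers had 3 of 15 (odds ratio 0.286, adjusted p = 0.0624), including the neuronal genes Map2 and Snap25. Pericyte and smooth muscle markers had 1 of 9, Notch3 (odds ratio 0.143, adjusted p = 0.0624 by Fisher's exact test). These calls moved with the distance rule. By nearest gene neither dental epithelium (odds ratio 0.333, adjusted p = 0.0870) nor immune markers (odds ratio 0.454, adjusted p = 0.189) passed, and immune markers did not by gene body or 10 kb either, with 8 of 16 (odds ratio 0.680, adjusted p = 0.559). At 3 kb glial and neuronal markers (odds ratio 0.235) and pericyte markers (odds ratio 0.117) passed, each with an adjusted p of 0.0264 by Fisher's exact test. For reference, 13 of 15 housekeeping genes had a window (86.7%, odds ratio 7.45, adjusted p = 0.00561), including Gapdh, Eef1a1, B2m, Gusb and Hprt. None of 1110 olfactory receptor genes had one (odds ratio 0, with an upper bound of 0.00345, adjusted p = 3.4e-313). Each list was compared with the other protein-coding genes by a two-sided Fisher's exact test adjusted over 16 lists, of which 9 passed 0.05. When windows with a higher-scoring motif site alone were counted, 1 list passed.

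**Figure D1:**
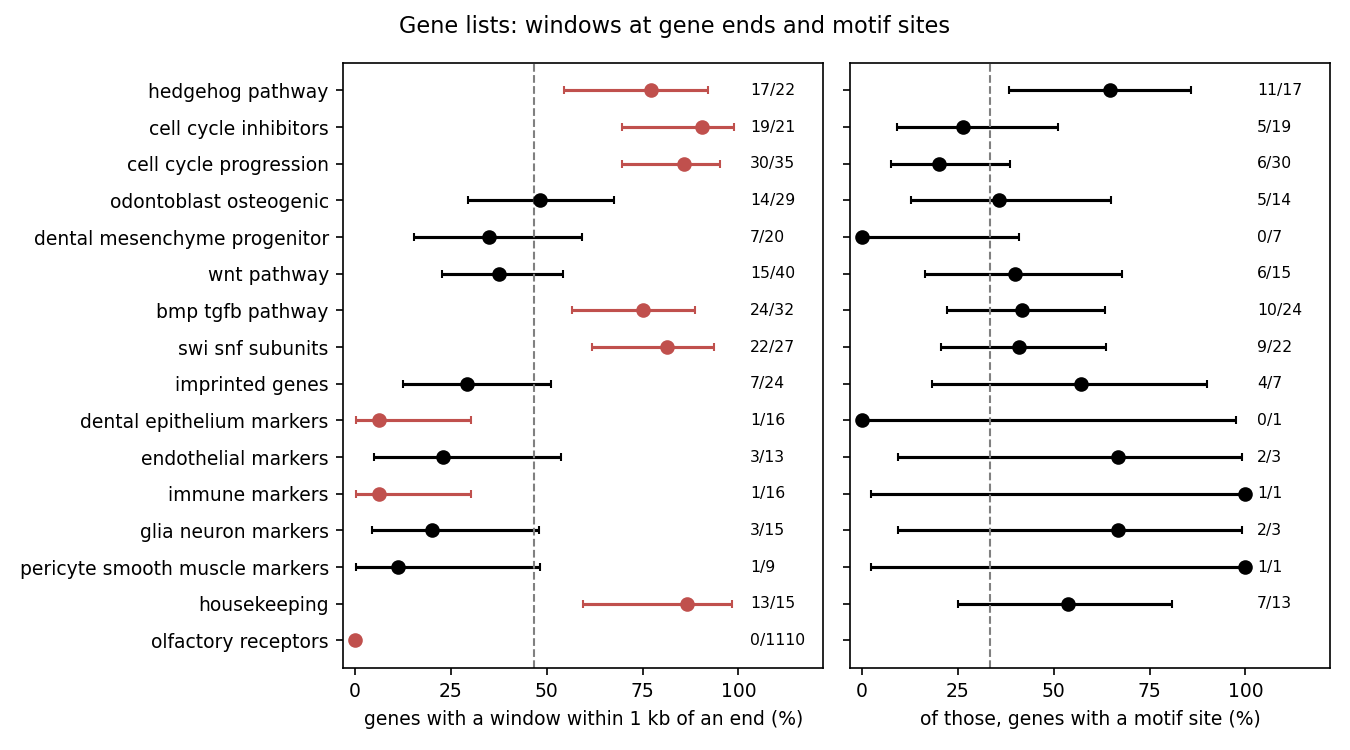
Percent of the genes of each list that had an open chromatin window within 1 kb of a gene end, and percent of the genes with a window whose windows held a motif site, with exact 95% intervals. The dashed line marks the share among all protein-coding genes for windows, and among all genes with a window for sites. Red marks an adjusted p under 0.05. Cell cycle inhibitors stood at 90.5% for windows, and hedgehog pathway genes at 64.7% for sites.

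Some genes held many windows, counted over the whole gene and not adjusted for its length. The 10 genes with the most assigned windows were Gm38510 with 13, Tex14 with 10, Sp140 with 8, Gm7592 and Zfp978 with 7 each, Bcas3, Pde4d and Rere with 6 each, and A530032D15Rik and Arhgap23 with 5 each, the last pair taken in alphabetical order from several genes tied at 5. Tex14 encodes a protein of germ cell intercellular bridges, Pde4d a phosphodiesterase of cyclic AMP, and Rere a nuclear receptor co-regulator. Pde4d runs from 108654177 to 109955969 on chromosome 13, so its 6 windows are to be read beside a median of 5 per megabase that held any. The windows of Rere held 7 motif sites and those of Pde4d held 0. Gm38510, Sp140, Gm7592 and A530032D15Rik lie within 1 Mb of each other on chromosome 1.

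The sites of the Plagl1 motif were 10 bp long, and their bases show which positions the search held fixed. All sites had G at position 6, counted from 1 at the 5′ end of the motif strand. G made up 99.5% of bases at positions 4 and 7, position 5 was G in 55.2% and A in 44.8%, and C made up 89.3%, 71.1% and 58.0% at positions 8, 9 and 10. Positions 1 to 3 held no base above 43.6%. Sites lay on the plus strand 2946 times and on the minus strand 2807 times (two-sided binomial p = 0.0688). Scores ran from 5.51 to 7.74 with a median of 5.94. Their positions along the window did not depart from uniform in a permutation test (p = 0.932).

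**Figure D2:**
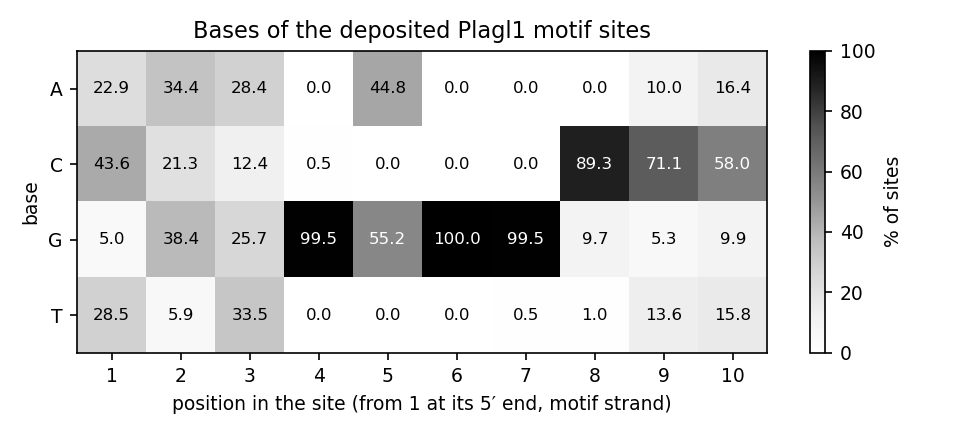
Percent of each base at each of the 10 positions of the 5753 motif sites, read on the motif strand. G was fixed at position 6 and reached 99.5% at positions 4 and 7, while positions 1 to 3 varied.

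The highest-scoring site, TATGAGGCCC with a score of 7.74, lay inside Trim7, which encodes a ubiquitin ligase, at chromosome 11, 48834453 to 48834462. The next 8 sites shared the sequence CATGGGGCCC and a score of 7.61. Their nearest genes were Ctdsp1, Ebf2, Vps51, Sh3glb2, Shf, Hacd4, Aplp1 and Hprt, where Ebf2 is a transcription factor of mesenchymal lineages and Hprt a purine salvage enzyme. The sequence AATGGGGCCC followed with a score of 7.59 at 7 sites, of which the one nearest Tbce, a tubulin folding cofactor, came first in the sort order of the file positions.

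**Figure D3:**
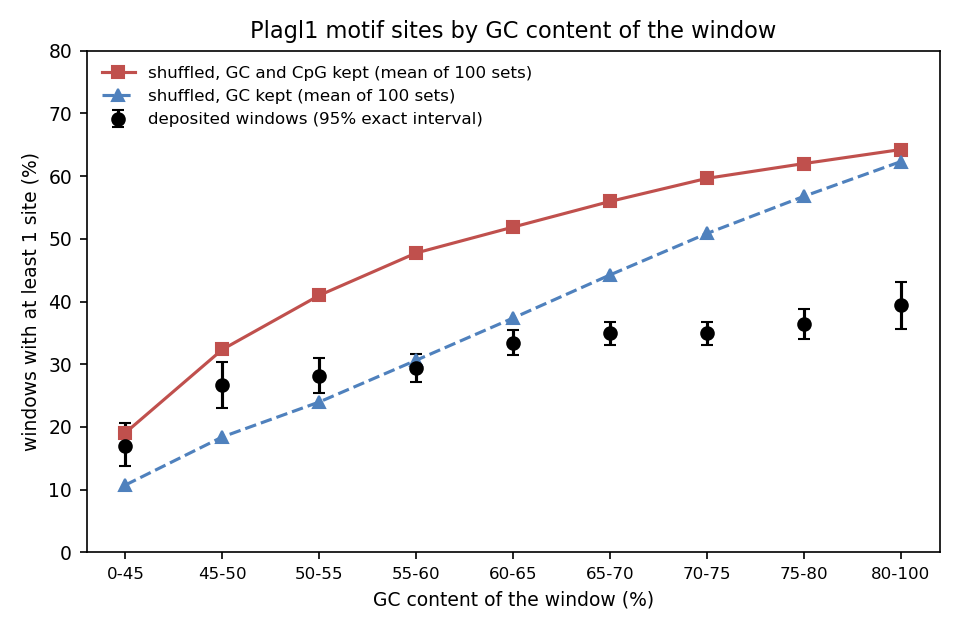
Percent of windows with at least 1 motif site by GC content of the window, in the observed windows (points, with exact 95% intervals) and as the mean of shuffled windows with the same GC and CpG content (squares) or the same GC content alone (triangles). The observed share rose from 17.0% to 39.4%, with shares below both shuffles in the windows of highest GC content and above the shuffle of GC content alone in those under 55% GC.

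Whether the windows held more or fewer Plagl1 motif sites than their base composition gives was tested against shuffled sequence. Windows with a site numbered 4444 of 13500 (32.9%, exact 95% interval 32.1 to 33.7), against 7116 ± 55.8 (SD, 100 shuffled sets) in windows shuffled with the same GC and CpG content. The ratio was 0.625, and the ratio of site counts, 5753 over 11323, was 0.508. The windows near gene ends stood at 0.608 of the shuffled number, those inside genes at 0.642 and those outside genes at 0.689. The empirical p was 0.0198, the smallest that 100 sets can give, in each of these cases. When the shuffles kept GC content alone, the ratio was 0.796, and windows outside genes turned to the other side, with 584 against 531 (ratio 1.10). So did the windows of low GC content, with 81 against 51.2 under 45% GC, 155 against 107 from 45 to 50% and 290 against 247 from 50 to 55%, each with an empirical p of 0.0198. Shuffled windows keep neither repeats nor other neighbouring base pairs, nor any imbalance of G against C or of A against T. Real genomic sequence was not used as a comparison, so the ratios describe a departure from these random sequences only.

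Individual site sequences lay on both sides of their shuffled counts. CCCGGGGCCC was the most frequent, with 117 sites against 175 in shuffled windows, followed by CGCGGGGCCC with 107 against 140. CCGGGGGCCC had 40 against 179 (ratio 0.224). In the other direction CAGGGGGCGC, which matches the core recognised by the insulator protein CTCF, had 84 against 58.1 (ratio 1.45), and CAGGAGGCCG had 41 against 23.6 (ratio 1.74). These sequences were picked out after the counts were seen. Over the 667 sequences searched, these 2 excesses had an empirical p of 0.653 and 0.505 from windows shuffled with GC and CpG kept. With GC alone kept, the empirical p was 0.0495 and 0.0990. With GC and CpG kept, 1 sequence, AAAGGGGCCG with 27 sites against 8.87, exceeded the largest excess of any sequence in every shuffled set. Its empirical p from the shuffled sets was 0.00990, the smallest that 100 sets can give. With GC alone kept, 9 sequences did, among them AAAGGGGCCG, TCTGGGGCTC with 30 against 9.05 and CCTGGGGCTC with 48 against 20.8.

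Windows with a site were about as frequent near genes as away from them. The share with a site was 32.8% (exact 95% interval 31.8 to 33.7) within 1 kb of a gene end, 33.8% (32 to 35.6) inside genes and 32.4% (30.3 to 34.6) outside genes. The odds ratio of windows near a gene end over all others was 0.980 (95% interval 0.907 to 1.06, Fisher's exact p = 0.612). Within the windows, GC and CpG content went with sites in opposite directions in a logistic model: 10 more percentage points of GC multiplied the odds of a site by 2.38 (95% interval 2.19 to 2.58), and 5 more CpG per 100 steps multiplied them by 0.448 (0.410 to 0.488). The median of the best score was 5.99 in both groups, with a difference near minus other of -0.00390 (two-sided permutation p = 0.538, with 2975 and 1469 windows). With only the highest-scoring window of each nearest gene kept, the difference was -0.0358 (permutation p = 0.00160, with 2844 and 1218 windows). Choosing windows by their score can itself move the medians, so this value is not a plain comparison of the classes.

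Among the genes with a window at an end, 3411 (33.4%) had a Plagl1 motif site in it, and the fixed lists were used to ask which groups had more or fewer. Hedgehog pathway genes had a site in 11 of 17 cases (64.7%, exact 95% interval 38.3 to 85.8), an odds ratio of 3.66 (95% interval 1.24 to 12.1). The raw Fisher's exact p was 0.00913, and adjusted over 15 lists it was 0.137, so the list did not pass. Smo held 2 sites (best score 6.82) in its window at chromosome 6, 29735817 to 29736017, Boc held 2 (best 6.15), Cdon 1 and Disp1 1, while Dhh and Evc held 0. Chosen after their values were seen, the other members with a site included the transcription factor Gli3, the Gli inhibitor Sufu, the acyltransferase Hhat, the ligand-release factor Scube2 (score 6.37), Evc2 (best score 7.07) and the ubiquitin ligase adaptor Spop.

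No other list passed for sites. Cell cycle inhibitors had a site in 5 of 19 (26.3%, odds ratio 0.711), which after their values were seen are named as Cdkn1b, Cdkn1c, E2f5, Gadd45b and Rbl1; Rb1, Cdkn2d, Tob1, Btg1, Btg2 and Ccng1 had 0 sites. Genes that drive the cycle had a site in 6 of 30 (20.0%, odds ratio 0.497), SWI/SNF subunits in 9 of 22 (odds ratio 1.38), and BMP and TGF-beta genes in 10 of 24 (odds ratio 1.42). Smad3 held 5 sites over its 4 assigned windows, none of them in the window at its gene end. Wnt genes had a site in 6 of 15 (odds ratio 1.33), odontoblast genes in 5 of 14 (odds ratio 1.11), dental mesenchyme genes in 0 of 7 (odds ratio 0, upper bound 1.38), imprinted genes in 4 of 7 (odds ratio 2.66) and housekeeping genes in 7 of 13 (odds ratio 2.33). Col1a1 held 3 sites (best score 7.34) in its window at chromosome 11, 94936119 to 94936319. The cell type markers held at most 3 genes with a window each. In that small group sites were found in 2 of 3 endothelial and 2 of 3 glial and neuronal genes, in Cd3d and in Notch3, but not in Ambn. Counting all protein-coding genes as the background, or a distance of 3 kb, or leaving out windows shared with a neighbouring gene, brought the hedgehog list past 0.05, with odds ratios of 5.43, 4.79 and 5.58, the 5.43 counting the excess of windows as well. Gene body or 10 kb (odds ratio 3.86, adjusted p = 0.137), a logistic model with GC, CpG and window number (odds ratio 3.31, adjusted p = 0.178) and higher-scoring sites (odds ratio 1.84, adjusted p = 0.860) did not. With a list made to have sites in 60% of its members, the test called it in 27.5% of 40 simulated sets of 10205 genes, so a difference of this size could be missed.

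**Figure D4:**
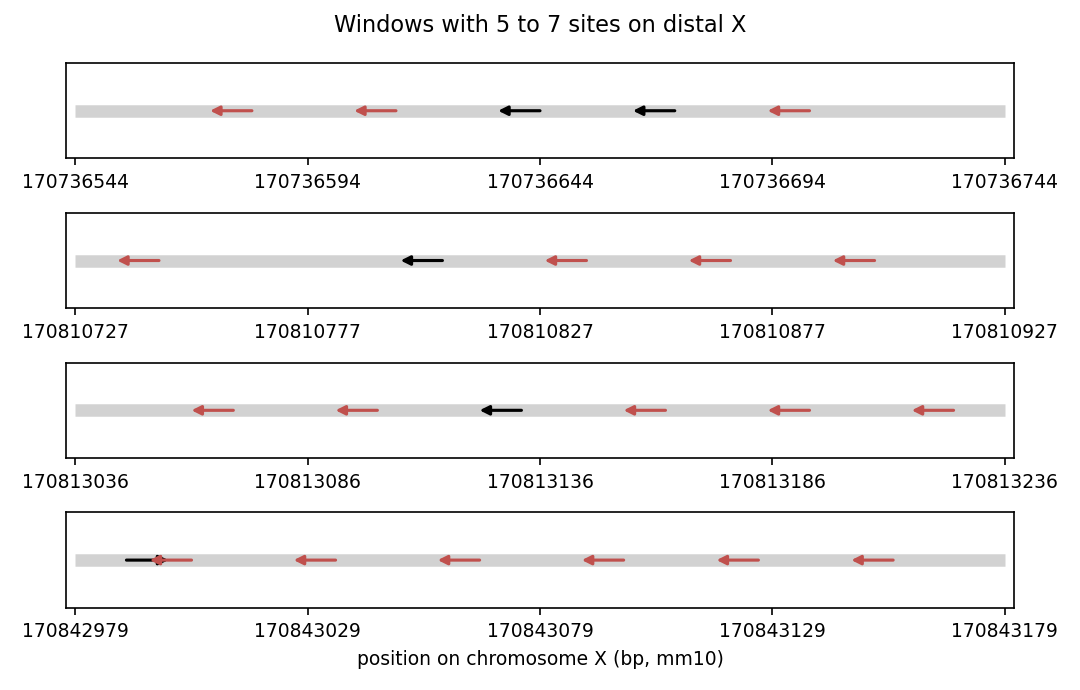
Position in mm10 of the motif sites in 4 windows on distal chromosome X, with windows as grey bars and sites as arrows in the direction of their strand, red for TGTGAGGCCC and black for other sequences. Of 19 gaps between neighbouring sites, 17 were 29 to 31 bp.

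Windows with many sites were rare, and 1 place held several of them. A site was seen once in 3389 windows, 2 sites in 852, 3 in 163, 4 in 32, and 5 or more in 8. Of those 8 windows, 4 lay on distal chromosome X between 170736544 and 170843179, where the nearest annotated gene was Asmt, which encodes the last enzyme of melatonin synthesis. These 4 windows, picked out after the counts were seen, held 23 sites, and 17 of the 19 gaps between neighbouring sites were 29 to 31 bp, mostly with the sequence TGTGAGGCCC.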

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

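The alternatives for site counts (but for the central 50 bp), site share by class and list tests of sites were chosen after the data were seen, and those for positions, windows at gene ends and scores before. Of the values that answer a comparison, 40 were held the same under an alternative, 4 moved and 4 gained a call. Of the 40, those with a p kept their direction and side of the threshold. Among them were the folds near gene ends (20.9 to 23.0 within 1 kb of protein-coding genes) and the ratio of windows with a site to shuffled windows (0.514 to 0.796). The 40 also hold file agreement and counts of passing lists, which for windows ran from 8 to 11 against 9. These have no direction and were held the same when close in size. Merging overlapping windows repeated the main values, since none overlap, and distances from any base of a window reused the p of the midpoint. Among single lists, 108 values kept both direction and side of the threshold, 5 gained a call and 11 lost one, of which 8 fell under the count of higher-scoring sites alone. The other 3 were dental epithelium and immune markers by nearest gene and immune markers by gene body or 10 kb. Calls were gained by glial and neuronal markers at 3 kb and by gene body or 10 kb (odds ratio 0.247, adjusted p = 0.0267), by pericyte markers at 3 kb and by nearest gene (odds ratio 0.125, adjusted p = 0.0429), and by housekeeping genes for sites with all protein-coding genes as background (odds ratio 4.75, adjusted p = 0.0239).

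With higher-scoring sites alone, 1 list passed for windows in place of 9, by construction, as fewer windows counted. For sites, 3 lists passed in place of 0 with all protein-coding genes as background, 1 with 3 kb, and 1 without windows shared with another gene. The hedgehog site odds ratio was then 5.43 (adjusted p = 0.00137), 4.79 (adjusted p = 0.0308) and 5.58 (adjusted p = 0.0252), but 1.84 (adjusted p = 0.860) with higher-scoring sites and 3.31 (adjusted p = 0.178) with GC, CpG and window number in a logistic model. The background of all protein-coding genes also counts the excess of windows at these genes; for the other changes the cause was not tested. With only the highest-scoring window of each nearest gene kept, the difference of median score was -0.0358 (permutation p = 0.00160). Under this choice the median of the other windows went from 5.99 to 6.03, while that near gene ends stayed at 5.99. The difference can therefore follow from choosing windows by score, and no other cause was tested.

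Lists that did not pass changed sides of an odds ratio of 1, and the cause was not tested. For windows these were odontoblast genes at 0.935 without receptors in the background, dental mesenchyme at 1.86 by nearest gene and 1.02 by gene body or 10 kb, Wnt at 1.67 and 1.26 under the same settings, and imprinted genes at 2.0 and 1.36, 1.11 with 3 kb and 1.51 with higher-scoring sites. For sites with all protein-coding genes as background these were cell cycle inhibitors at 1.69, cycle drivers at 1.12, Wnt at 0.956, endothelial at 0.985 and glial and neuronal at 0.833. By gene body or 10 kb they were cycle drivers at 1.03, Wnt at 0.728 and dental epithelium at 1.38, and in the logistic model odontoblast genes at 0.920.

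No paired analysis was possible because the groups share 1 replicate number and the tables carry no column per library. Placements matched on GC content, a model with promoter GC content, the search for fixed G/C-rich cores, the classes and gene assignment of the authors, and the mutant and control alternatives were not run, for want of a genome sequence or of values per library. Depth per library is unknown, so no value has a depth limit attached.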

Other observations

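Gene families that the fixed lists leave out were tested after the data were seen, for windows at gene ends, over 19 families. Families of general cell function had windows at most of their genes: 36 of 40 proteasome subunits (odds ratio 10.3, adjusted p = 4.0e-08), 69 of 78 mitochondrial ribosomal proteins (odds ratio 8.83, adjusted p = 9.3e-14), 35 of 40 NADH dehydrogenase subunits (odds ratio 8.04, adjusted p = 1.8e-07) and 79 of 97 cytosolic ribosomal proteins (odds ratio 5.06, adjusted p = 7.9e-12). Intraflagellar transport and Bardet-Biedl genes, which build and serve the primary cilium where hedgehog signals are received, had windows in 19 of 22 cases (odds ratio 7.26, adjusted p = 0.000245). Kinesins had 31 of 38 (odds ratio 5.08, adjusted p = 2.1e-05), translation initiation factors 47 of 56 (odds ratio 6.00, adjusted p = 2.5e-08), Zfp zinc finger genes 271 of 397 (odds ratio 2.50, adjusted p = 1.9e-17) and histones 60 of 102 (odds ratio 1.64, adjusted p = 0.0225).

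Of the remaining families, 6 had fewer windows than other genes. None of 39 Hox genes, the homeobox genes that pattern the body axis and whose expression the jaw lacks, had a window at an end (odds ratio 0, upper bound 0.113, adjusted p = 8.8e-11). Fgf ligands had 3 of 22 (odds ratio 0.181, adjusted p = 0.00292), collagens 13 of 44 (odds ratio 0.479, adjusted p = 0.0298), keratins 1 of 53 (odds ratio 0.0219, adjusted p = 1.2e-12), claudins 2 of 35 (odds ratio 0.0692, adjusted p = 3.1e-07) and vomeronasal receptors 2 of 353 (odds ratio 0.00633, adjusted p = 7.7e-92). Sox genes with 7 of 19, Fox genes with 19 of 44, Tbx genes with 3 of 13 and solute carriers with 178 of 375 did not differ (odds ratios 0.668, 0.870, 0.343 and 1.03). No family passed for motif sites. The lowest raw p there was 0.0479, for 2 of 19 intraflagellar transport and Bardet-Biedl genes (adjusted p = 0.33, odds ratio 0.234). Windows were densest on chromosome 1 between 85000001 and 86000000, with 49 windows against a median of 5 per megabase that held any. Of these, 4 (8.16%) lay within 1 kb of a gene end, and their median GC content was 47.8%.

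The excess of hedgehog genes with a Plagl1 motif site was weighed against 3 explanations, with predictions written before each test. GC content, CpG content and number of windows per gene give 6.16 expected genes with a site (95% range 3 to 10). The 11 found lay above that range, with a tail p of 0.0151 under the logistic model. That p was not adjusted for picking this list from those tested. With the same properties in a logistic model of each list, the odds ratio was 3.31, against 3.66 without them, and its p adjusted over the lists was 0.178. The count and the odds ratio argue against these 3 properties as the whole source of the excess in this list. The adjusted p bears on chance over the lists instead. Windows shared with a neighbouring gene are argued against, as the odds ratio without them was 5.58 with a lower bound of 1.65. Chance over the lists tested stays open and could account for the pattern, since the p adjusted over the lists was 0.137. The groups of the design give no biological explanation that could be tested on pooled windows.

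The site sequence CAGGGGGCGC, which matches a CTCF core, was found 84 times against 58.1 in shuffled windows. A test over the 667 sequences searched was written after the counts were seen. Shuffled windows gave as large an excess of some sequence with an empirical p of 0.653 with GC and CpG kept and 0.0495 with GC alone kept. Base composition therefore stays open. If CTCF sites among the regions were the source, its sites should lie away from gene ends and near window centres. Of these sites, 53.6% lay over 1 kb from a gene end against 33.8% of other sites (permutation p = 0.00035), but their median distance from the window centre was 49.0 bp against 48.5 bp (permutation p = 0.947). With 1 prediction met and the other not, CTCF sites cannot be told apart from other sources by these values.

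The windows with 5 or more sites were weighed against a tandem repeat and base composition, where the repeat test and the test on distal chromosome X were written after the values were seen. Of gaps between neighbouring sites in these 8 windows, 54.3% (19 of 35) were 29 to 31 bp, with 17 of 19 on distal X and 2 of 16 in the other 4 windows. This range was read from the same gaps, so it cannot count for a tandem repeat, which stays open as the source of the 8 windows. On distal X the same sequence did recur: TGTGAGGCCC made up 3 of 5, 4 of 5, 5 of 6 and 6 of 7 sites of the windows. All sites of this sequence there lay on the minus strand, and in the window from 170813036 all 5 gaps were 31 bp. In these 4 windows the sites were thus arranged in tandem, which describes their positions and is not a test. For base composition, 8 such windows were found where shuffled windows gave 52 to 93, so this test does not decide, because composition alone would give more. Among 230 windows with the GC and CpG content of the distal X windows, 4 held 5 or more sites. That number lay within the 0 to 5 of windows shuffled with GC and CpG kept (mean 1.35) but above the 0 of every set with GC alone kept. By this count, which leaves out the spacing, strand and sequence of the sites, base composition cannot be told apart from other sources there. No biological explanation was tested.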
